A study of Daphnia magna with 392 samples.

How the data were processed

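Whole Daphnia magna, water fleas of 72 h of age, were kept for 24 h in water with 1 of 18 per- and polyfluoroalkyl substances (PFAS) or with solvent alone, at 0.33% dimethylsulfoxide or methanol. Nominal concentrations ran from 0.03 to 100 µM in steps of equal size on a log scale, and the labels also give a concentration measured for each treatment, in µg/L, which is used here. Per the labels, each of 3 replicate plates held the series of 2 substances and their shared controls, immobile animals were taken out at the end, and the homogenates of up to 5 animals per treatment and plate (8 for controls) were pooled for 1 library. RNA was selected by poly(A) and made into Lexogen CORALL libraries. The labels list 392 samples, of which 387 have a column in the tables and 5 belong to no group and have none. The replicate number is the plate.

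The authors demultiplexed with bcl2fastq 2.20.0, trimmed with Trim Galore 0.6.6, aligned with STAR 2.7.10a, sorted with SAMtools 1.15.1, counted with HTSeq 2.0.1, inspected quality with FastQC and MultiQC 1.12, and filtered and normalized each substance's table with edgeR, whose version is not stated. The genome build is not given in the sources used here, so no coordinates are printed. The 20 deposited tables hold log2 values of reads scaled per library with a pseudocount of 1, by the authors. In columns whose first line, the concentration, exceeds 100 µg/L, the deposited unit is recorded as a score, because that line is no log2 value, while the gene lines of these columns are log2 as in the others. Within each library, 2 to the power of the value, less 1, was a whole multiple of 1 step for 100% of the low values (tolerance 0.1 read, reach 20 reads). That step gave the reads per gene. Control libraries that appear in 2 tables had equal recovered reads for every gene both tables hold. For PFOS and FC10diol the table from which the submitters removed a treatment after quality control was the main one, and the full table was an alternative. 1 column, a plate 2 control of PFHpA in the PFPeA table, was not used because its substance has no series here; whether it served as the third PFPeA control is not stated in the labels. The 2 PFPeA controls used are libraries the labels name after PFTrDA and also list with the PFPeA table. A name from another substance therefore does not by itself set the unused column apart from them. No alternative with that column as a control was run.

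The tables held 18152 to 20342 genes each and 21328 together. Of these, 20897 (97.98%) matched a gene of the reference annotation ASM2063170v1.1, which was used for gene types and for which genes are neighbours. It gives 13 of the genes a name that is not an ID, all encoded in the mitochondrial genome, and no product names, so other genes are given by ID and type. Of 36 gene lists fixed by product name, 1, the mitochondrially encoded protein genes, had the 5 measured members needed for a test.

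Each table was fitted by itself in R 4.3.3 with limma 3.58.1 (lmFit, eBayes with a mean-variance trend, 1 coefficient per concentration group, 1 spread per gene over all groups). P-values were 2-sided and adjusted by Benjamini-Hochberg within each substance, and genes with an adjusted p below 0.05 are called changed. The comparisons were the highest concentration against the controls and the slope on the rank of the measured concentration. A point of departure took the genes with a called slope and a change of at least 1.5-fold. For each gene a monotone fit of the group means was read where it departs from the control mean by 1 residual SD, on the log scale of concentration. The 10th percentile over at least 20 genes was reported, with a 95% range from 100 resamplings of libraries. Gene lists were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, adjusted over all lists and substances. Pairs of related substances were compared by the difference of their changes at the highest concentration, in 1 fit over the genes of both tables. Where a pair shares its controls, each table was first centred on them. Genes called in the same direction against at least 4 of the 10 separate sets of controls were counted and set against 10000 shuffles of which genes carry the calls. Changes are the highest concentration minus control on the log2 scale. These choices, the lists and the rule for named genes were fixed before the data were examined. The rule names, for each substance, up to 2 IDs that rose and 2 that fell, by size of change, among called genes with every highest-concentration library beyond every control, and for each called list the 2 members with the smallest p in the called direction and the member with the smallest p against it.

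The steps were tested on simulated data made from the tables. The single genes changed were drawn from those above the median level of their table, with normal noise. Recovery of lower genes, and with libraries that deviate, was not simulated. With 50 genes changed by 2 on the log2 scale, the comparison at the highest concentration recovered 54% for N-EtFOSA-M, 74% for PFTDoDA, 48% for PFTP and 66% for PFOS. With a change of 4 it recovered 92% or more in these 4 tables. For genes simulated to change from 911 µg/L, with the next lower concentration at 212 µg/L, the point of departure came out at 91.3 µg/L, below the simulated concentration, so the procedure reads low. A list of 13 genes moved by 1 was detected, and 6 of 100 unchanged lists passed 0.05. The simulated genes varied independently of each other, while the mitochondrially encoded list had estimated correlations of 0.437 to 0.872, by substance. The simulation therefore cannot show that the preset correlation keeps its error rate for that list.

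The plates pair the samples across groups. Residuals of libraries from the same plate had a median correlation of 0.00685, against -0.00347 between plates. The mean was higher within plates in 13 of 18 tables and above 0.1 in 0. Residuals sum to 0 within a group, so the value between plates is tied to that within plates and is no separate baseline. The count of 13 thus reflects the sign of the value within plates alone. The highest concentration, the slope, the gene lists and the pairs were repeated with a replicate block, the plate as an additive term; the points of departure and the count over control sets were not. Further alternatives fixed beforehand were leaving out each plate and each control or highest library in turn, dropping the lowest 25% of genes by mean, a pseudocount of 4, centring each library on its median, a robust fit without the mean-variance trend, the full tables, pooling the 2 equal highest concentrations of PFTrDA, 2 residual SD, the 25th lowest gene and a 2-fold change for the point of departure, and at least 3 or 5 control sets. Chosen after the data were seen were limma voom on the recovered reads with the authors' effective library sizes or with total read numbers, library quality weights, the 3 lowest concentrations in place of the controls, and leaving out 5 libraries whose median correlation with their table lies over 0.05 below that table's median. The same holds for calls at each concentration, the comparison with the next lower concentration, lists by gene type and by neighbouring genes, the mitochondrially encoded list of N-EtFOSA-M without single libraries, and the mitochondrial tRNA genes against the 3 lowest concentrations. A count model on raw reads was not run, since the tables are log2 values. No group has 4 or more samples, so no test for a single deviating sample was made. Figures were drawn with matplotlib 3.10.9.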

Results

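The series measured polyadenylated RNA of whole Daphnia magna after exposure to 18 PFAS, to find the concentrations at which transcription departs from that of control animals. Each substance has a solvent control and up to 7 measured concentrations, mostly with 1 library from each of 3 plates. Of the groups, 116 had 3 libraries, 19 had 2 and 1 had 1. PFPeA and PFPB had 2 control libraries, and 6:2FTS, PFHxS and PFPB had 2 libraries at the highest concentration. Several tables share control libraries, so the 18 series rest on 10 sets of controls. PFNA, PFTrDA and PFPeA draw on 1 set, although the labels put 2 substances on a plate.

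The 406 library columns, in which a shared control counts in each of its tables, held 1.36 to 120 M reads in the genes of their table, with a median of 17.5 M. Annotated rRNA genes took 5.39% to 65.9% of them, with a median of 12.7%. Between 278 and 8790 genes of a table were at 0 in a library. The 2 libraries with the most genes at 0 were both at a highest concentration. The plate 2 library of FC8diol had 8790 such genes at 18.0 M reads, and the plate 3 library of 6:2FTS had 8494 at 1.36 M. The median standard error of a gene's change at the highest concentration lay between 0.453 and 0.651 on the log2 scale, by substance.

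**Figure D1:**
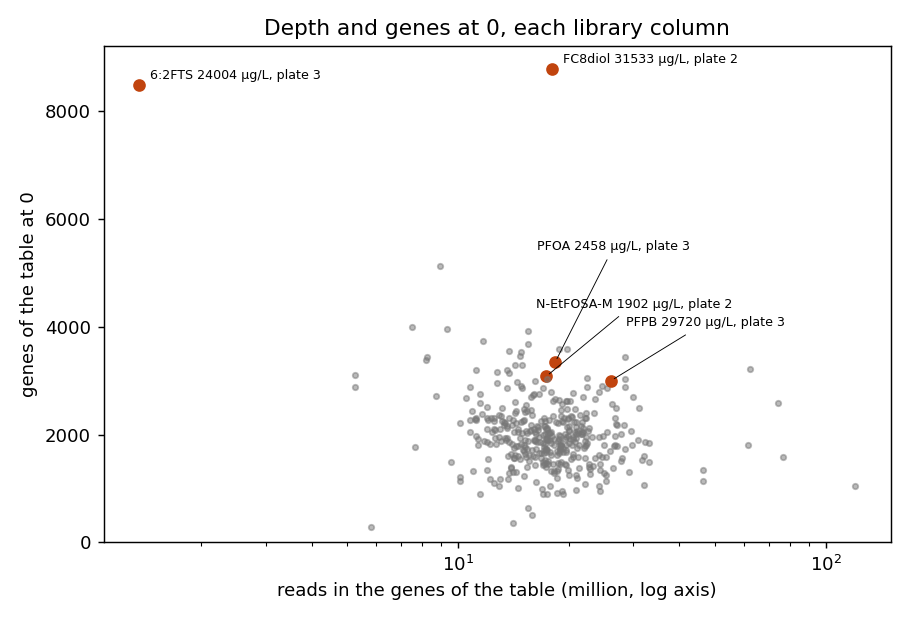
Reads in the genes of the table (M, log axis) against the number of genes at 0, with 1 point for each of the 406 library columns. The 5 labelled points are the libraries whose correlation with their table lies furthest below the median of that table; those of FC8diol (8790 genes at 0) and 6:2FTS (8494) lie above all others.

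The first comparison asked which genes differ from control at the highest concentration. N-EtFOSA-M (N-ethylperfluorooctanesulfonamide) had 754 changed genes, PFTDoDA 416 and PFTP 135. 8:2FTS, the 8:2 fluorotelomer sulfonic acid, had 32, PFPeA (perfluoropentanoic acid) 24 and PFHxS (perfluorohexanesulfonic acid) 22. FC10diol had 4, FHxSA (perfluorohexanesulfonamide) 2, and 6:2FTS, PFNA (perfluorononanoic acid) and PFOA (perfluorooctanoic acid) 1 each. The highest measured concentrations ran from 1012 µg/L for PFTrDA to 49039 µg/L for FC10diol, so these counts stand at different exposures, and the substances were not ranked against each other by a test.

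**Figure D2:**
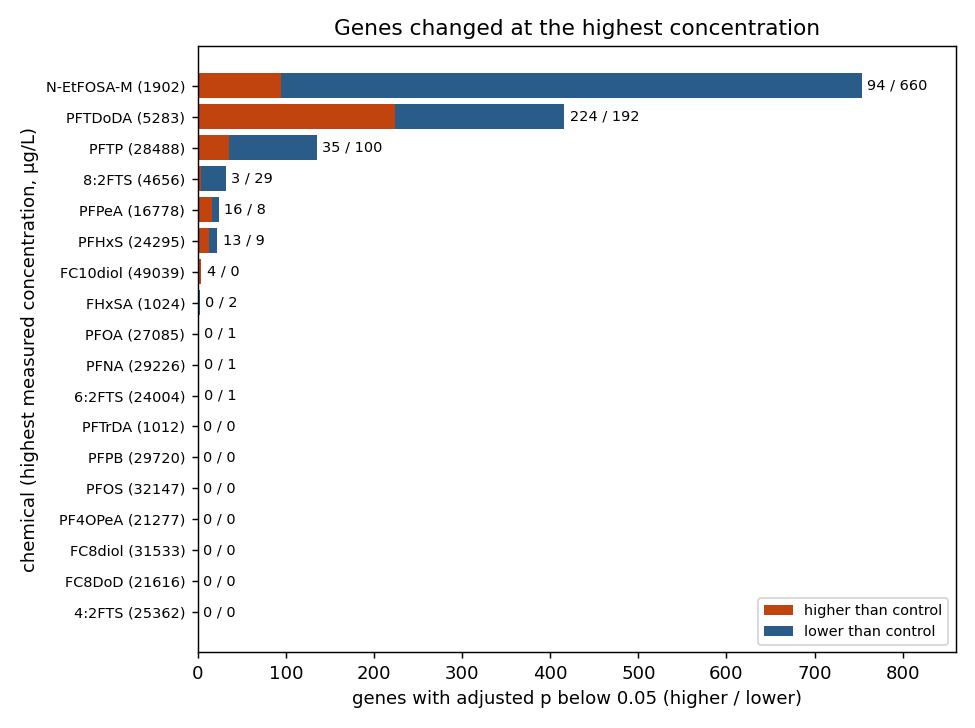
Number of genes with an adjusted p below 0.05 at the highest concentration against control, for each of 18 substances, split into higher and lower. The highest measured concentration in µg/L stands in parentheses; N-EtFOSA-M has 94 higher and 660 lower genes.

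At 1902 µg/L of N-EtFOSA-M, 660 genes fell and 94 rose. The protein-coding gene LOC116917378 fell by 8.00 ± 0.37 (SE, n = 3 against 3, adjusted p = 5.11e-14), from a mean log2 value of 8.45 ± 0.30 (SD) in controls to 0.45 ± 0.56. LOC116932186, also protein-coding, stood at 7.52 ± 0.59 (SD, n = 3) in controls and was listed at 0 in all 3 exposed libraries (adjusted p = 5.64e-14). Among the rises, LOC116917317 increased by 4.09 ± 1.10 (SE, n = 3 against 3, adjusted p = 0.031) and LOC116929938 by 3.99 ± 0.99 (SE, n = 3 against 3, adjusted p = 0.0171). The falls of LOC116917378 and LOC116932186 were called in 19 of 19 alternatives, the rise of LOC116917317 in 9 of 19 (adjusted p 0.0193 to 0.237) and that of LOC116929938 in 10 of 19 (0.0104 to 0.245). The median value of a library differed by -0.348 between exposed and control libraries, while the median change over all genes was 0.02581; with each library centred on its median, 433 genes were higher and 471 lower, 565 of them among the 754. The count was 452 without the plate 3 control, 483 without plate 1, 337 without plate 3, and 424 (79 higher, 345 lower) with voom and the authors' effective library sizes.

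The next lower concentration of N-EtFOSA-M measured 1830 µg/L, a ratio of 1.04. Nominal steps were wider than this, and whether the animals met exposures further apart than the measured values was not tested. Both named falls were close to control there: LOC116917378 had a mean of 8.40 ± 0.32 (SD, n = 3) and LOC116932186 of 7.07 ± 0.50 (SD, n = 3) at 1830 µg/L. The named rises show no onset at these concentrations, since both averaged above control at every concentration. LOC116929938 stood at 2.09 ± 1.36 (SD, n = 3) in controls, 4.14 ± 0.87 at 3 µg/L and 4.37 ± 1.32 at 1830 µg/L. LOC116917317 stood at 0.16 ± 0.27 (SD, n = 3) in controls, 2.62 ± 1.73 at 3 µg/L, 2.88 ± 2.24 at 147 µg/L and 1.51 ± 2.21 at 1830 µg/L, where 1 library was at 4.05 and the others at 0 and 0.47. Between these 2 concentrations 1002 genes differed, 181 higher and 821 lower at 1902 µg/L. Against control, 29 genes were called at 1830 µg/L, 14 of them also at 1902 µg/L, and the 754 genes had a median change in their direction of 0.201 there, against 2.45 at 1902 µg/L.

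At 5283 µg/L of PFTDoDA, 224 genes rose and 192 fell. LOC116925200, annotated as misc_RNA, rose by 6.53 ± 0.43 (SE, n = 3 against 3, adjusted p = 2.81e-09), from 6.64 ± 0.61 (SD) to 13.17 ± 0.20, and stood at 10.25 ± 1.08 (SD, n = 3) at 1820 µg/L. The protein-coding gene LOC116920578 rose by 5.94 ± 0.63 (SE, n = 3 against 3, adjusted p = 3.41e-06). LOC116933741 fell by 4.84 ± 0.63 (SE, n = 3 against 3, adjusted p = 4.98e-05) and LOC116935348 by 4.55 ± 0.79 (SE, n = 3 against 3, adjusted p = 0.00138), both protein-coding. Both rises were called in 18 of 18 alternatives and both falls in 16 of 18 (adjusted p up to 0.227 and 0.0933). At 1820 µg/L, 4 genes were called against control, and 411 differed between 1820 and 5283 µg/L (200 higher, 211 lower). The count at 5283 µg/L was 273 without the plate 3 control, 245, 111 and 182 without plates 1, 2 and 3, and 245 with voom.

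At 28488 µg/L of PFTP, 100 genes fell and 35 rose. LOC116931234 fell by 5.48 ± 0.52 (SE, n = 3 against 3, adjusted p = 4.13e-06) and its neighbour LOC116931233 by 4.62 ± 0.50 (SE, n = 3 against 3, adjusted p = 9.49e-06), from control means of 9.99 ± 0.10 and 10.16 ± 0.16 (SD, n = 3). LOC116921261 rose by 6.50 ± 1.12 (SE, n = 3 against 3, adjusted p = 0.0033) and LOC123473821 by 6.12 ± 0.91 (SE, n = 3 against 3, adjusted p = 0.000539). All 4 are protein-coding. Both falls were called in 18 of 18 alternatives, the rises in 14 and 16 of 18 (adjusted p up to 0.222 and 0.0973). At 8204 µg/L, 2 genes were called, and LOC116921261 stood at 4.39 ± 1.14 (SD, n = 3) there, between 0.99 ± 0.89 in controls and 7.48 ± 1.70 at 28488 µg/L. The count at 28488 µg/L was 78 without the plate 1 library of that concentration, 83 without its plate 2 library, 81 without the plate 2 control, 33, 24 and 44 without plates 1, 2 and 3, and 87 in the robust fit.

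**Figure D3:**
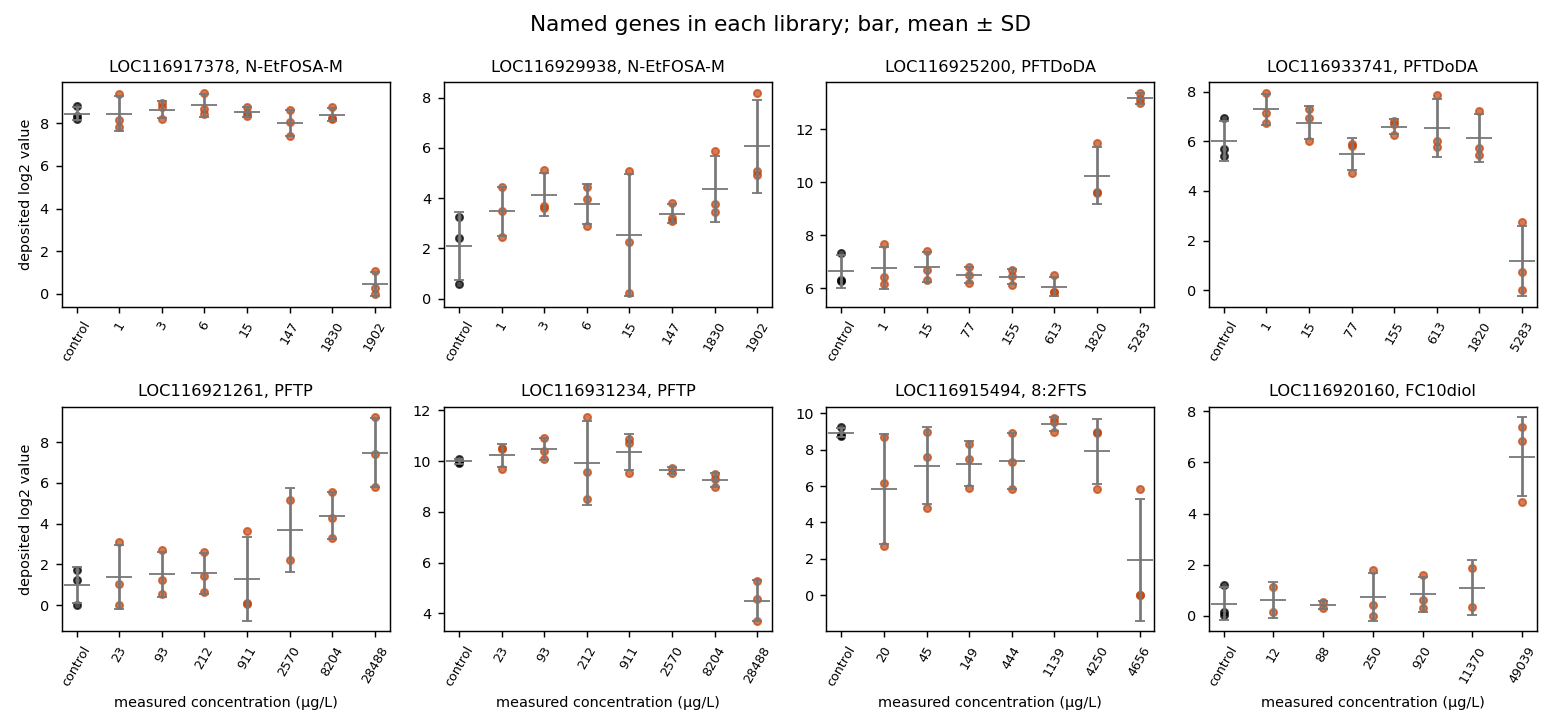
Deposited log2 values of 8 named genes in each library, by measured concentration in µg/L, with mean and SD; black points are controls. In the N-EtFOSA-M panel LOC116917378 averages 8.40 at 1830 µg/L and 0.45 at 1902 µg/L.

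8:2FTS at 4656 µg/L had 29 lower and 3 higher genes. LOC116915494 fell by 7.00 ± 1.35 (SE, n = 3 against 3, adjusted p = 0.0426), from 8.94 ± 0.26 (SD) to 1.94 ± 3.37, and LOC116933062 by 6.50 ± 1.37 (SE, n = 3 against 3, adjusted p = 0.0477; 0.063 with the replicate block, range 5.47e-05 to 0.834 over its alternatives). LOC123467078 rose by 1.76 ± 0.34 (SE, n = 3 against 3, adjusted p = 0.0426) and LOC116927124 by 1.72 ± 0.34 (SE, n = 3 against 3, adjusted p = 0.0426). All 4 are protein-coding. The SD of 3.37 shows how far the exposed libraries lay apart: the count was 264 without the plate 3 library at 4656 µg/L and 0 without its plate 1 or plate 2 library, 0, 1 and 0 without the control of plate 1, 2 and 3, and 0, 0 and 212 without those whole plates. It was 0 with voom and in the robust fit, 3 with a pseudocount of 4, 147 with library quality weights, and 3 against the 3 lowest concentrations in place of the controls, 2 of them among the 32. Against 4250 µg/L, limma called 0 genes at 4656 µg/L, with 1184 at an unadjusted p under 0.05; no other tool was run on that contrast.

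PFPeA at 16778 µg/L had 16 higher and 8 lower genes against 2 controls, which belong to the PFTrDA set. Annotated rRNA genes took 35.3% and 16.8% of the reads in these controls and 8.39% to 14.7% in the PFPeA libraries, so a difference between plates is not separated from the exposure here, and a plate number does not show that control and exposed animals shared a plate. LOC116924958 rose by 3.65 ± 0.55 (SE, n = 2 against 3, adjusted p = 0.0152) and LOC116921694 by 2.87 ± 0.47 (SE, n = 2 against 3, adjusted p = 0.0152). LOC116929462 fell from 2.89 ± 0.67 to 0.19 ± 0.19 (SD, n = 2 against 3, adjusted p = 0.0152) and LOC116935757 by 2.30 ± 0.37 (SE, n = 2 against 3, adjusted p = 0.0152), and all 4 are protein-coding. PFPeA also had calls at every lower concentration, from 11 genes at 58 µg/L to 48 at 5637 µg/L, and 27 at the lowest, 9 µg/L. Against the 3 lowest concentrations in place of the controls, 1 gene was called and 0 of the 24 were among it, and their median change fell from 2.14 to 0.137. The count was 55 without the plate 1 control, 337 without the plate 3 control, 7, 0 and 0 without the highest library of plate 1, 2 and 3, 8, 0 and 84 without those plates, 13 with quality weights, 14 without the lowest 25% of genes, and with voom 0 or, with total read numbers, 39.

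PFHxS at 24295 µg/L had 13 higher and 9 lower genes, with 2 exposed libraries. LOC116934809 rose by 3.70 ± 0.63 (SE, n = 3 against 2, adjusted p = 0.0203) and LOC116936373 by 3.50 ± 0.62 (SE, n = 3 against 2, adjusted p = 0.0234). Both rises were already present at the lowest concentration. LOC116934809 averaged 0.88 in controls, 3.00 at 30 µg/L and 4.58 at 24295 µg/L. LOC116936373 averaged 0.42, 3.36 and 3.92 in these groups, and 1.66 at 9076 µg/L. The rises thus show no onset at 24295 µg/L. LOC123466533 fell by 3.81 ± 0.76 (SE, n = 3 against 2, adjusted p = 0.0473) and LOC116916368 by 3.42 ± 0.64 (SE, n = 3 against 2, adjusted p = 0.0419). All 4 are protein-coding. With the replicate block both falls had an adjusted p of 0.0618 and were no longer called (ranges over their alternatives 0.041 to 0.25 and 0.0212 to 0.363). Against the 3 lowest concentrations 7 genes were called, 2 of them among the 22. The count was 44 without the plate 2 library at 24295 µg/L, 5, 11 and 34 without the control of plate 1, 2 and 3, 0 without any 1 plate, 7 in the robust fit, 4 with quality weights, and 38 without the lowest 25% of genes.

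**Figure D4:**
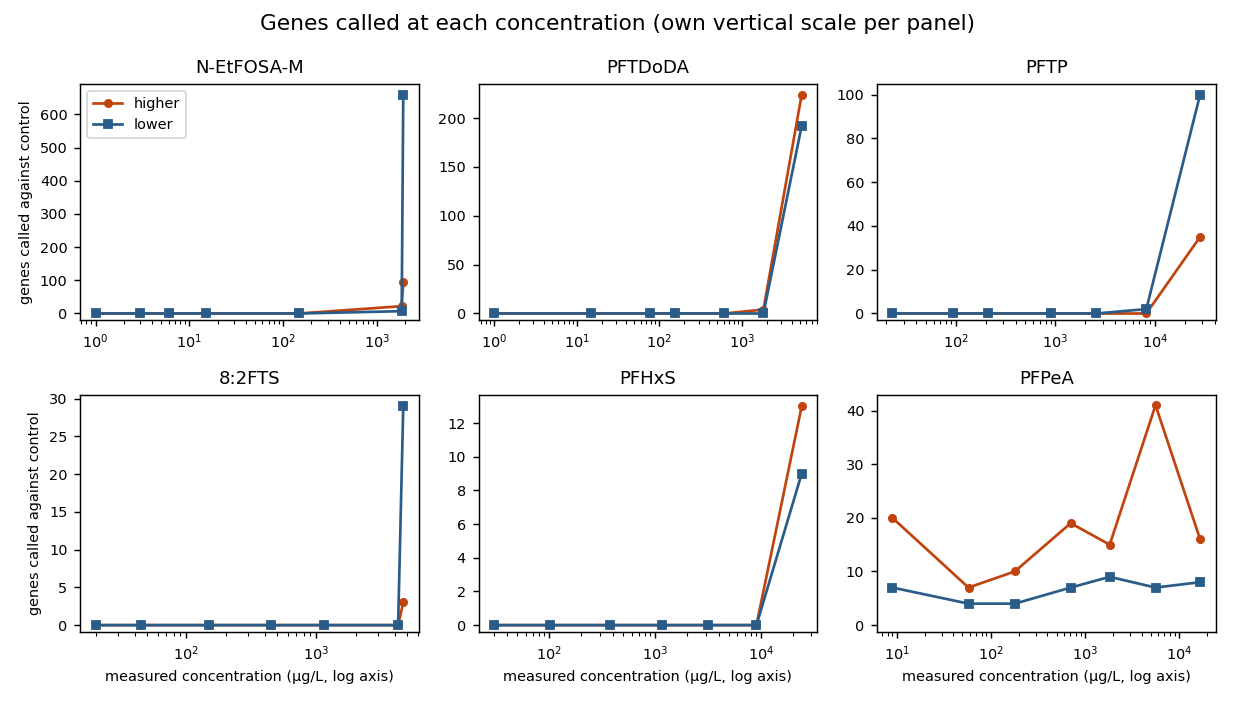
Genes called against control at each measured concentration (µg/L, log axis) for 6 substances, higher and lower apart; each panel has its own vertical scale. For PFTDoDA and PFTP calls appear at the 2 highest concentrations alone, while PFPeA has 11 to 48 at every concentration.

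The other substances had few calls. With FC10diol at 49039 µg/L, 4 genes rose, among them LOC116920160 by 5.74 ± 0.77 (SE, n = 3 against 3, adjusted p = 0.00832) and LOC116932569 by 4.52 ± 0.72 (SE, n = 3 against 3, adjusted p = 0.0406; 0.0647 with the replicate block, range 0.00184 to 0.871). With FHxSA at 1024 µg/L, LOC116928363 fell by 2.33 ± 0.37 (SE, n = 3 against 3, adjusted p = 0.0243) and LOC116928429 fell by 2.30 ± 0.39 (SE, n = 3 against 3, adjusted p = 0.0341; 0.0527 with the block, range 0.000659 to 0.819). Of the single calls, LOC123475579 in 6:2FTS fell from 2.59 ± 0.77 (SD, n = 3) and the lncRNA gene LOC123472238 in PFNA from 1.61 ± 0.53 (SD, n = 3) to 0 in every exposed library. The lncRNA gene LOC123474444 in PFOA fell by 1.81 ± 0.29 (SE, n = 3 against 3, adjusted p = 0.0254). With the block these 3 had adjusted p of 0.0653, 0.0961 and 0.0689 and were not called (ranges 0.000531 to 1, 0.0124 to 0.992, and 0.00522 to 1). The 4 genes of FC10diol were also called against the 3 lowest concentrations, among 24 there, and the 2 of FHxSA among 43. The single calls of 6:2FTS, PFNA and PFOA were not: their changes went from 2.59, 1.61 and 1.81 to 0.186, 0.102 and 0.0277 in size, since these 3 genes lay near 0 at every concentration and above it in controls alone. Single libraries decided these counts. Without 1 library FC10diol had 0 (plate 2 or 3 control) or 9 genes (highest, plate 1), and FHxSA 0 (highest plate 1, or control of plate 1 or 3) or 4 (highest, plate 3). 6:2FTS had 0 (highest plate 3, or control of plate 1 or 2), 2 (plate 3 control) or 6713 (highest plate 1, which leaves the library with 1.36 M reads). PFNA had 0 without any highest library or the plate 1 control, and PFOA 0 without any highest library or the control of plate 2 or 3, and 2 without the plate 1 control.

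In 7 substances limma called 0 genes at the highest concentration. Genes at an unadjusted p under 0.05 numbered 1443 for 4:2FTS, 1034 for FC8DoD, 2662 for FC8diol, 1627 for PF4OPeA, 1113 for PFOS (perfluorooctanesulfonic acid), 2042 for PFPB and 1447 for PFTrDA (perfluorotridecanoic acid). Voom called 1 gene for PFPB and 0 for the other 6 with the authors' effective library sizes, and with total read numbers 136 for FC8diol, 1 for PFPB and 0 for the rest. Other settings of limma called some: 2 for FC8diol with the replicate block, 7 for PFOS with quality weights, 1 for FC8DoD and 3 for PFPB in the robust fit, and with a pseudocount of 4 there were 4 for 4:2FTS, 1 for PF4OPeA and 2 for PFPB. Against the 3 lowest concentrations there were 76 for FC8diol, 84 for PFPB, 9 for PFTrDA, 3 for FC8DoD and PF4OPeA, 1 for PFOS and 0 for 4:2FTS. For PFOS, 66% of genes simulated to change by 2 and 10% of those simulated to change by 1 were recovered, all above the median level of the table. Changes of 1 were thus mostly not detectable there, and lower genes were not simulated. The other 6 substances were not simulated. Leaving out 1 library of the highest group gave 1971 genes for FC8diol (without plate 3), 586 for PFPB (without plate 2), 15 for 4:2FTS (without plate 1), 5 for PFTrDA (without plate 1), 2 for FC8DoD (without plate 3) and for PF4OPeA 2 or 1 (without plate 2 or 3). Leaving out a whole plate gave 407 and 1 for FC8diol (plates 3 and 1) and 1 for PF4OPeA (plate 3). Leaving out 1 control gave 70 and 4 for PFPB (plates 2 and 3) and 1 for FC8diol (plates 2 and 3), 4:2FTS (plate 3), PF4OPeA (plate 2) and PFTrDA (plate 2).

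The 13 protein genes of the mitochondrial genome, which encode subunits of the respiratory chain and of ATP synthase, were tested as a list fixed before the data were examined. In N-EtFOSA-M all 13 had positive changes with a median of 0.96, and 5 were called over all genes tested, 12 adjusted over the list alone. ND4L rose by 1.56 ± 0.316 (SE, n = 3 against 3, adjusted p = 0.00249) and ATP6 by 1.03 ± 0.242 (SE, n = 3 against 3, adjusted p = 0.011). The median change over all genes was 0.02581; with each library centred on its median, which adds 0.348 to every change, the list's median is 1.31. Camera placed the list above other genes (adjusted p = 1.01e-07), and fry, which asks whether the members move one way, gave an adjusted p of 0.0258. With an estimated correlation the adjusted p was 0.748. Without the plate 3 library at 1902 µg/L, 12 of 13 were positive with a median of 0.578 and 1 was called. Without the control of plate 2 or 3, 3 and 2 were called, and 5 without the plate 2 library at 1902 µg/L, which stands apart from its table (median 1.16). These fits were chosen after the data were seen. The rRNA genes took 25.1% to 44.1% of the reads at 1902 µg/L and 17.9% to 22.5% in controls, and 2 of 7 of them were called higher (median 0.771). The 13 genes took 3.90% to 6.01% and 2.93% to 3.75%.

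In the 8 other substances that passed with the preset correlation, the adjusted p with an estimated correlation was 0.748 or 0.778 and fry gave 0.256 to 0.555, so none of the following held there. In PFTDoDA the list was above other genes with the preset correlation (13 of 13 positive, median 0.322, adjusted p = 0.00107; 0.748 with the estimated one), with 1 member called over all genes and 2 adjusted over the list alone; ND4 rose by 0.631 ± 0.157 (SE, n = 3 against 3, adjusted p = 0.0301) and ND1 had 0.548 ± 0.183 (SE, n = 3 against 3, adjusted p = 0.157). In 8:2FTS all 13 were positive with a median of 0.184 (adjusted p = 0.0182; 0.778 estimated), and 0 were called in either way of adjusting. The list lay below other genes in 6 substances, with 0 members called over all genes: 4:2FTS (median -0.583, 0 of 13 positive, adjusted p = 5.3e-05), FHxSA (-0.405, 0 positive, 0.000353), PFTrDA (-0.40, 0 positive, 0.00034), PFHxS (-0.445, 1 positive, 0.00122), PFPeA (-0.323, 1 positive, 0.00632) and PFOS (-0.281, 1 positive, 0.02). Adjusted over the list alone, 4 were lower and 1 higher in PFHxS, 1 lower in FHxSA and 0 in the other 4. The other 9 substances had an adjusted p of 0.0953 or more.

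**Figure D5:**
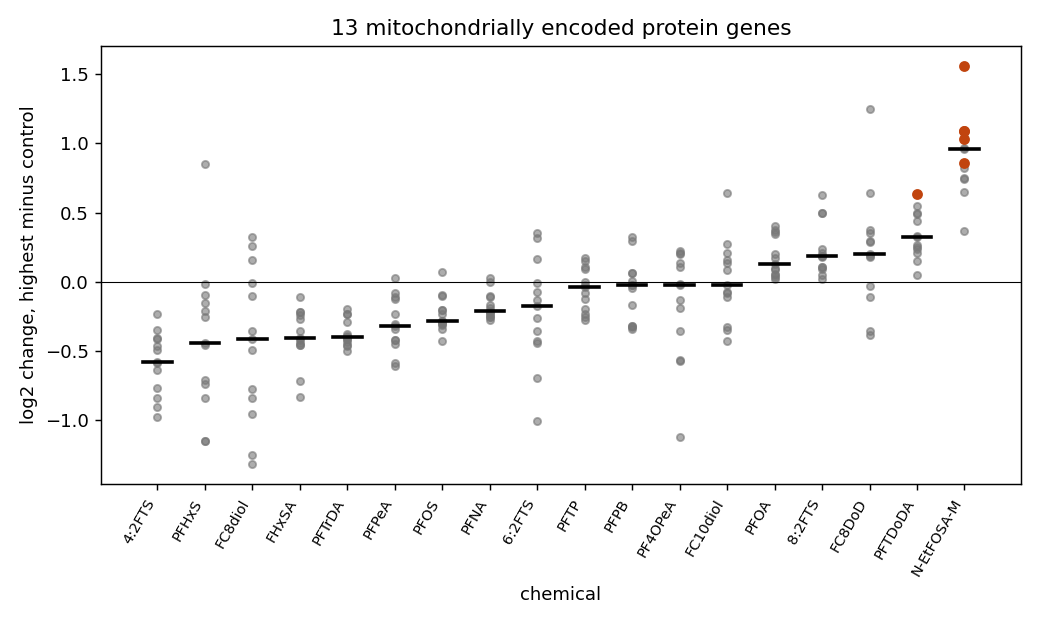
Change at the highest concentration against control (log2) of the 13 mitochondrially encoded protein genes in each of 18 substances; black bars are medians and coloured points have an adjusted p below 0.05. N-EtFOSA-M has the highest median, 0.96, with 5 coloured points, and 4:2FTS the lowest, -0.583, with 0.

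The second comparison asked which genes have a slope on the rank of the concentration. N-EtFOSA-M had 290 such genes (30 with a rising and 260 with a falling slope), PFTP 185 (31 and 154), PFTDoDA 20 (12 and 8), PFHxS 4 rising and PFTrDA 1 rising. LOC116928429 fell with N-EtFOSA-M (slope -0.738 per rank, adjusted p = 0.00172) and with PFTP (slope -0.24, adjusted p = 0.0382), and LOC116921261 rose with PFTP (slope 0.799, adjusted p = 0.00271). LOC116925200 rose with PFTDoDA (slope 0.725, adjusted p = 0.0368). A called slope need not be gradual. LOC116925200 averaged 6.64 in controls, 6.06 at 613 µg/L, 10.25 at 1820 µg/L and 13.17 at 5283 µg/L. LOC116917378 also had a called slope, with N-EtFOSA-M (-0.695, adjusted p = 0.0356). It averaged 8.45 in controls, 8.40 at 1830 µg/L and 0.45 at 1902 µg/L. LOC116921261 changed over several steps, with 3.69 at 2570 µg/L and 4.39 at 8204 µg/L. How many slopes rest on the highest concentration alone was not counted. The other 13 substances had 0 genes by limma, with 814 to 1968 at an unadjusted p under 0.05, and no other tool was run on the slope. The trend depended on having all plates: without plates 1, 2 and 3 it called 19, 1 and 6 genes for N-EtFOSA-M, 34, 21 and 26 for PFTP, and 0 for PFTDoDA, PFHxS and PFTrDA in every case. Without the plate 2 library of N-EtFOSA-M at 1902 µg/L, 31 were called. With the replicate block PFTDoDA had 11 and PFHxS 7, and with median centring PFTP had 116.

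Points of departure could be read for the 3 substances with at least 20 such genes. They were 5.54 µg/L for N-EtFOSA-M (290 genes), 5.83 µg/L for PFTDoDA (20 genes) and 48.93 µg/L for PFTP (183 genes), within series that began at 1, 1 and 23 µg/L. The median gene departed at 93.77, 543.9 and 1178 µg/L. The resampled ranges were 1 to 3.34, 1 to 4.35 (92 of 100 resamplings gave a value) and 23 to 38.3 µg/L and do not hold the estimates, and the procedure read low on simulated data, below the highest simulated concentration without change. The values are therefore not taken as concentrations at which transcription departs. Around that of N-EtFOSA-M, from 1 to 147 µg/L, limma called 0 genes against control, with 719 to 972 at an unadjusted p under 0.05. At 2 residual SD they became 162.1, 837.7 and 1393 µg/L. With a pseudocount of 4 PFTDoDA moved to 68.21 µg/L. Leaving out any plate left N-EtFOSA-M and PFTDoDA with too few genes, and PFTP at 189.5, 23 and 53.24 µg/L without plates 1, 2 and 3.

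The third comparison set related substances side by side at their highest concentrations, each against its controls. PFOS and N-EtFOSA-M, a sulfonic acid and an N-ethyl sulfonamide, differed in 403 genes, with the PFOS change above that of N-EtFOSA-M in 334 and below it in 69, at 32147 and 1902 µg/L. The count was 208, 287 and 146 without plates 1, 2 and 3. PFHxS (24295 µg/L) lay above PFOS (32147 µg/L), its analog with a longer chain, in 18 genes and below it in 0; with the block there were 30, and without plates 1, 2 and 3 there were 0, 2 and 0. PFHxS also lay above FHxSA (1024 µg/L), which has a sulfonamide in place of the sulfonic acid, in 36 genes, with 0 without plate 1 or 2 and 50 without plate 3. PFPeA (16778 µg/L) and PFOA (27085 µg/L), carboxylic acids of different chain length, differed in 3 genes, for which the doubt about the PFPeA controls holds too, with 0 without plate 1 or 2 and 19 without plate 3.

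PFOA and PFOS, which differ in head group and share their controls, differed in 0 genes by limma at 27085 and 32147 µg/L (677 at an unadjusted p under 0.05, median half-width of the 95% interval 1.25 on the log2 scale). PFOA and PFNA (29226 µg/L) differed in 0 (807 at an unadjusted p under 0.05, half-width 1.75). No other tool was run on pairs, and intervals of this width leave room for differences of more than 1. In data simulated for PFOS and N-EtFOSA-M, which have separate controls, the pair comparison recovered 0% of genes differing by 1 and 30% of those differing by 2. It recovered 68% at 3 and 84% at 4, all for genes above the median level. The pairs of PFOA were not simulated, so a count of 0 there says little about differences of this size. The fluorotelomer sulfonic acids 4:2FTS (25362 µg/L) and 6:2FTS (24004 µg/L) differed in 1247 genes, 1105 of them lower in 6:2FTS. That count was 1 without the plate 3 library of 6:2FTS with 1.36 M reads, 7360 without plate 1, and 0 without plate 2 or 3. 6:2FTS and 8:2FTS (4656 µg/L) differed in 1 gene, 4833 without plate 1, and 0 without plate 2 or 3 or without that library. FC8diol (31533 µg/L) and FC10diol (49039 µg/L) differed in 97 genes, 45 with the FC8diol change above and 52 below; there were 16 without the FC8diol library with 8790 genes at 0, and 8, 0 and 1042 without plates 1, 2 and 3.

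The last comparison asked which genes respond to several substances with separate controls. Against at least 4 of the 10 control sets 0 genes were called in 1 direction. Against at least 3 there were 23, of which 22 were lower and 1 higher. Shuffles gave at most 3 (permutation p = 1e-04, the smallest that 10000 shuffles can give). These shuffles, and the counts expected by chance below, take every gene of a table as equally likely to be called. Genes differ in this: lncRNA genes made up 8.75% of the calls of N-EtFOSA-M and 18.2% of the genes tested. How far the sharing exceeds chance is therefore not settled by them. LOC116931234 was lower in N-EtFOSA-M (-2.43), PFTDoDA (-2.92) and PFTP (-5.48). LOC116928429 was lower in FHxSA (-2.30), N-EtFOSA-M (-6.59) and PFTP (-1.99). LOC116920578 was higher in N-EtFOSA-M (3.84) and PFTDoDA (5.94), while LOC116925200 was higher in PFTDoDA (6.53) and PFTP (2.97) and lower in N-EtFOSA-M (-2.65). Between substances, N-EtFOSA-M and PFTDoDA shared 68 lower genes where 7.03 are expected by chance, N-EtFOSA-M and PFTP 61 (3.67 expected), and PFTDoDA and PFTP 26 (1.07 expected). Shared higher genes numbered 8, 1 and 8, in each pair also above the number expected by chance, so the sharing was not confined to falls. Genes called in opposite directions numbered 16, 4 and 2 (9.26, 1.81 and 1.62 expected), also above expectation in each pair. Whether rises were shared beyond chance is therefore not settled by these counts. Of the genes called in the first of each pair, 68.1%, 77.8% and 71% had the same sign in the second.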

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

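The tests of the scaling, of the plate 2 library and of the control libraries in this part were chosen only after the results were seen. The tests of depth, of the number of starting molecules and of a few abundant genes were written before their results were known.

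N-EtFOSA-M differed from PFOS in 403 genes, and in N-EtFOSA-M itself 660 genes fell while 94 rose. Sequencing depth argues poorly for this imbalance, since thinning control and exposed libraries to 8.22 M reads left 6.99 falls per rise (678 and 97). Leaving out the plate 2 library gave 7.31 falls per rise, which argues against that library. Against the 3 lowest concentrations the genes that fell kept 0.98 of their median change, which argues against the control libraries as the cause of these falls. The ratio there was 2.3 (1133 and 492), between the bounds set, so a part of the controls in the imbalance itself cannot be told apart from other causes. With each library centred on its median the ratio was 1.09 (471 and 433), a value that a difference in scaling between libraries would give. Centring adds 0.348 to every change whatever its cause, so this ratio cannot tell scaling from other causes. The balance of falls and rises also changed between voom with the authors' effective library sizes and voom with total read numbers. It therefore depends on the scaling chosen. Of the genes called after centring, 351 fell and 95 rose by over 2, a ratio of 3.69 (3.59 to 7.07 without 1 plate), which argues against the scaling as the cause for large changes; for smaller ones it stays open. A general loss of RNA from many genes in exposed animals would give the same values and was not tested.

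Differences between substances stood out in 1247 genes for 4:2FTS and 6:2FTS, in 1 for 6:2FTS and 8:2FTS, and in 97 for FC8diol and FC10diol, and 1 highest library in each of 6:2FTS and FC8diol held many genes at 0. In FC8diol plate 2, 8790 genes were at 0 where 611.8 are expected at its 18.0 M reads, and the 10 most abundant genes took 28.8% of its reads (14.1% to 64.9% in the others), both against depth or a few genes as the cause. The zeros over groups of genes by level followed those of a library with 0.104 M starting molecules to within 0.0867, so few starting molecules may be the cause. In 6:2FTS plate 3, 8494 genes were at 0 where depth gives 2826, and its 10 most abundant genes took 16.3% (14.6% to 33.4%), which argues against both as the whole cause; the gap was 0.151, so few molecules cannot be told apart from other causes there, because it lies between the bounds set. Whether animals died or RNA decayed at these concentrations was not tested.

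PFHxS differed from PFOS in 18 genes and from FHxSA in 36, PFPeA differed from PFOA in 3, and for such counts the control libraries themselves could be what stands apart. This was tested on the genes that single substances had called against their controls. The genes that differed between the pairs were not tested in this way. The genes called in N-EtFOSA-M, PFTDoDA and PFTP kept 0.95, 0.917 and 0.928 of their median change against the 3 lowest concentrations. That argues against the controls as the cause of these calls. Those of PFPeA kept 0.0638, so its 24 calls may come from its 2 controls, which the labels name after PFTrDA and in which rRNA genes took 35.3% and 16.8% of the reads (8.39% to 14.7% in the PFPeA libraries). Those of 8:2FTS and PFHxS kept 0.648 and 0.651, and the explanations cannot be told apart there, because the values lie between the bounds set. A response that is already full at the lowest concentrations would look alike for PFPeA and was not tested.

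The submitters removed 1 treatment of FC10diol after quality control, at 2687 µg/L, which the comparisons above do not use. In the full table its 1 library had 25 genes called against control, 25 of them higher. The spread in that test comes from the other groups alone, so the count holds only if this library varies as they do, which cannot be checked with 1.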

How the results depend on the processing

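Both voom settings, the library quality weights, the 3 lowest concentrations as the reference and leaving out the 5 libraries that stand apart were chosen after seeing the data. No gene named by size of change, and no call of the mitochondrially encoded list, reversed its direction under the alternatives run for it. The mitochondrial tRNA list, which passed with the preset correlation in 4:2FTS and 6:2FTS, did change sign there. Against the 3 lowest concentrations its median went from 0.356 to -0.0939 and from 0.241 to -0.132. Over all called genes signs were counted against the 3 lowest concentrations alone: 17 of 24 were kept in PFPeA, 413 of 416 in PFTDoDA, 134 of 135 in PFTP, and all in the other substances with calls. Of the genes named by size of change, LOC116917378, LOC116932186, LOC116925200, LOC116920578, LOC116931234 and LOC116931233 stayed past the threshold in all alternatives run for them. Every other gene named in that way lost its call in at least 1. The mitochondrial genes named with their list were not followed over these alternatives. Counts below are genes called at the highest concentration unless a trend, a pair or a point of departure is named, and a count not listed stayed within 1.5 times of that in the report. Fewer genes tested or fewer libraries are part of some settings, and beyond that the cause was not tested. Where 1 library remains in a group, it is assumed to vary like the other groups.

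With the replicate block 6:2FTS, PFNA and PFOA had 0, FHxSA 1, FC8diol 2, the trend of PFHxS 7, the trend of PFTDoDA 11, and the pair PFHxS and PFOS 30. It kept 698 of the 754 calls of N-EtFOSA-M, 377 of 416 of PFTDoDA, 121 of 135 of PFTP, 26 of 32 of 8:2FTS, 20 of 24 of PFPeA, 13 of 22 of PFHxS and 3 of 4 of FC10diol. Without the lowest 25% of genes 6:2FTS, PFNA and PFOA had 0, PFPeA 14 and PFHxS 38, and the trend gave 15 for FHxSA, 1 for PFOS and 0 for PFTrDA. A pseudocount of 4 gave 4 for 4:2FTS, 7 for 6:2FTS, 3 for 8:2FTS, 1 for PF4OPeA, 0 for PFNA and 2 for PFPB, and a trend of 1 for FHxSA and 0 for PFTrDA. Median centring gave 0 for 6:2FTS and PFOA, 1 for FHxSA, and a trend of 116 for PFTP and 0 for PFTrDA. The robust fit gave 0 for 6:2FTS, 8:2FTS, FHxSA and PFNA, 1 for FC8DoD, 3 for PFPB, 7 for PFHxS and 87 for PFTP. Pooling the equal highest concentrations of PFTrDA and the full tables of PFOS and FC10diol left the counts within 1.5 times.

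Voom with the authors' effective sizes gave 0 for 6:2FTS, 8:2FTS, FHxSA, PFNA, PFOA and PFPeA, 1 for FC10diol and PFPB, 424 for N-EtFOSA-M and 245 for PFTDoDA. With total read numbers it gave 0 for 6:2FTS, 8:2FTS, FHxSA, PFNA and PFOA, 1 for FC10diol and PFPB, 136 for FC8diol and 39 for PFPeA; N-EtFOSA-M had 832 (17 higher, 815 lower), 561 of them among the 754. Quality weights gave 0 for 6:2FTS, 147 for 8:2FTS, 7 for FHxSA, 4 for PFHxS, 7 for PFOS and 13 for PFPeA. Against the 3 lowest concentrations there were 1545 for 6:2FTS, 3 for 8:2FTS, 24 for FC10diol, 3 for FC8DoD, 76 for FC8diol, 43 for FHxSA, 1625 for N-EtFOSA-M (703 shared), 3 for PF4OPeA, 7 for PFHxS, 0 for PFNA, 4 for PFOA, 1 for PFOS, 84 for PFPB, 1 for PFPeA, 758 for PFTDoDA (359 shared), 371 for PFTP (118 shared) and 9 for PFTrDA, while 4:2FTS stayed at 0. Without the libraries that stand apart 6:2FTS had 0, the trend of N-EtFOSA-M 31, and the pairs 7 for PFPeA and PFOA, 1 for 4:2FTS and 6:2FTS, 0 for 6:2FTS and 8:2FTS and 16 for FC8diol and FC10diol.

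Leaving out 1 replicate, as a plate or as a single control or highest library, gave counts from 337 to 792 for N-EtFOSA-M, 111 to 392 for PFTDoDA, 24 to 117 for PFTP, 0 to 264 for 8:2FTS, 0 to 337 for PFPeA, 0 to 44 for PFHxS, 0 to 1971 for FC8diol, 0 to 6812 for 6:2FTS, 0 to 586 for PFPB, 0 to 15 for 4:2FTS, 0 to 9 for FC10diol, 0 to 5 for PFTrDA, 0 to 4 for FHxSA, 0 to 2 for PF4OPeA, FC8DoD and PFOA, and 0 to 1 for PFNA; PFOS stayed at 0. The trend ranged from 1 to 19 for N-EtFOSA-M, 21 to 34 for PFTP and 0 to 1 for 4:2FTS, and was 0 for PFTDoDA, PFHxS and PFTrDA without any plate. Pairs ranged from 0 to 7360 (4:2FTS and 6:2FTS), 0 to 4833 (6:2FTS and 8:2FTS), 0 to 1042 (FC8diol and FC10diol), 0 to 50 (PFHxS and FHxSA), 0 to 2 (PFHxS and PFOS), 0 to 19 (PFPeA and PFOA) and 146 to 287 (PFOS and N-EtFOSA-M).

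The points of departure at 2 residual SD were 162.1 µg/L for N-EtFOSA-M, 837.7 for PFTDoDA and 1393 for PFTP. A pseudocount of 4 gave 68.21 for PFTDoDA and 42.57 for PFTP; the 25th lowest gene 157.1 and a 2-fold change 61.74 for PFTP, whose range was 23 to 189.5 without 1 plate. No value was reached for N-EtFOSA-M without any 1 plate, for PFTDoDA without any 1 plate, by the 25th gene or with a 2-fold change, and in the full tables of PFOS and FC10diol. The mitochondrially encoded list had, with an estimated correlation, an adjusted p of 0.748 in 4:2FTS, FHxSA, N-EtFOSA-M, PFHxS, PFTDoDA and PFTrDA and 0.778 in 8:2FTS, PFOS and PFPeA. With fry it was 0.256 in 4:2FTS, FHxSA, PFHxS, PFTDoDA and PFTrDA, 0.417 in 8:2FTS, 0.555 in PFOS and 0.375 in PFPeA, and it held in N-EtFOSA-M alone. At least 3 control sets gave 23 genes where at least 4 gave 0. Depth limits what low genes can show: at the 1.36 M reads of 1 library of 6:2FTS, 2826 genes of its table are expected at 0, and the 8494 seen there are more than depth gives.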

Other observations

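The tests of gene types and of neighbouring genes in this part were chosen only after the calls were seen, while the test of the spread and the splits of the samples were written before their results were known.

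Genes annotated as long non-coding RNA were rare among the calls of 3 substances. They made up 8.75% of the called genes of N-EtFOSA-M against 18.2% of those tested (Fisher's exact p = 1.52e-13), 6.49% in PFTDoDA against 18.2% (exact p = 3.29e-12) and 5.93% in PFTP against 18.0% (exact p = 6.63e-05). In 8:2FTS they made up 6.25% against 18.3% (exact p = 0.105), in PFPeA 16.7% against 18.7% (exact p = 1) and in PFHxS 22.7% against 18.7% (exact p = 0.588). Genes are not independent replicates, and a lower level of such genes would lower their chance of a call. In FC8DoD, where 0 single genes were called, the 22 tRNA genes of the mitochondrial genome all had positive changes at 21616 µg/L, with a median of 1.18. Camera gave an adjusted p of 5.23e-13, an estimated correlation 0.00408, and fry 0.000473; 5 were called when adjusted over the list alone. In PFHxS, which shares its 3 controls, 16 of the 22 were positive with a median of 0.798, camera gave 2.55e-05, an estimated correlation 0.154 and fry 0.0159, and 7 were called over the list alone. The list had a median above 0 in 17 of 18 substances and passed with the preset correlation in 9. Against the 3 lowest concentrations it was above 0 in 14. Of those 9, its median was no longer positive in 4:2FTS (-0.0939) and 6:2FTS (-0.132), was smaller in PFPeA (0.295 from 0.556), and kept 0.765 of its size in FC8diol, 0.936 in FHxSA, 1.2 in PFOA and 1.38 in 8:2FTS. It kept 0.909 of its size in FC8DoD (1.07, 21 of 22 positive), which argues against the shared controls as its whole cause, and 0.394 in PFHxS (0.314, 16 of 22 positive). Of 125 tests of lists by gene type and substance, 17 passed with the preset correlation, and of these 1 also with the estimated one, that of FC8DoD. The libraries were selected for poly(A), so such RNA is measured through whatever share of it was selected.

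In 4 of the 6 substances with over 20 calls, called genes lay next to each other more often than in shuffles of the calls. These shuffles take every gene of a table as equally likely to be called, and genes differ in this. How far the pairs exceed chance is therefore not settled by them. Neighbouring pairs called in 1 direction numbered 62 in N-EtFOSA-M (23.5 on average over 10000 shuffles), 35 in PFTDoDA (4.71), 5 in 8:2FTS (0.0418) and 5 in PFTP (0.619; permutation p = 5e-04). For N-EtFOSA-M, PFTDoDA and 8:2FTS the permutation p was 1e-04, the smallest the shuffles can give. PFHxS and PFPeA had 0 such pairs among 22 and 24 called genes (permutation p = 1). Among the named genes, LOC116931233 and LOC116931234 are such a pair in PFTP, and LOC116935348 opens a run of 3 in PFTDoDA. Reads shared between neighbouring copies were not tested.

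A hypothesis was that genes lower in several substances are ones that vary between libraries of a group anyway. For the 29 genes lower in 8:2FTS, the residual SD in 7 other tables lay at a median percentile of 96.4 among 500 genes of like level, with all 29 above 75, so that spread may be the source of these calls. Of the genes called in 8:2FTS, 29 of 30 had the same sign in N-EtFOSA-M and 29 of 30 in PFTP. The number was 29 of 32 in PFPeA and 8 of 31 in PFHxS. These genes thus mostly moved together, so they are not separate observations. For the 22 genes lower against 3 control sets the median percentile was 69.3 (30.4 to 98.3), which decides nothing. The 7 tables were picked by hand among those with at most 1 call.

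Other splits of the 3 control and 3 highest libraries number 10 with the real one, too few for a share under 0.05. As many genes came up in 1 of 10 for N-EtFOSA-M (754, highest other 1), PFTDoDA (416, other 31), PFTP (135, other 1), 8:2FTS (32, other 2), FC10diol (4, other 0) and FHxSA (2, other 0), and in 2 of 10 for PFNA and PFOA (1, other 1). For the substances with 0 genes it was 10 of 10, the highest other being 4 for PF4OPeA, 2 for FC8DoD, 1 for 4:2FTS and PFTrDA, and 0 for FC8diol and PFOS. A camera p of the mitochondrial list as small as the real one came up in 1 of 10 for N-EtFOSA-M (5.61e-09, smallest other 2.67e-07) and FHxSA (7.84e-05, other 0.00522). It came up in 2 for 4:2FTS (5.88e-06, other 1.01e-06) and PFTDoDA (0.000297, other 5.11e-08). The number was 3 for 8:2FTS (0.00809, other 0.000281) and PFTrDA (5.66e-05, other 3.94e-09), and 7 for PFOS (0.01, other 1.05e-08). Splits that mix control and exposed libraries thus also gave very small camera p with the preset correlation, in PFTrDA below that of N-EtFOSA-M. Such a p alone therefore does not mark the exposure. For pairs with 3 libraries on each side, as many genes came up in 1 of 10 for PFOS and N-EtFOSA-M (403, other 0). The same held for PFPeA and PFOA (3, other 0). The number was 2 for FC8diol and FC10diol (97, other 930, which points to a structure of the samples), and 10 for PFOA with PFOS (0, other 1) and with PFNA.

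For the trend, 100 orders of the libraries were counted, the real one included. As many genes came up in 1 of 100 for N-EtFOSA-M (290, highest other 8), PFTP (185, other 1) and PFHxS (4, other 1), in 2 for PFTDoDA (20, other 88) and in 3 for PFTrDA (1, other 1). Chance orders are excluded at a share of 0.05 for N-EtFOSA-M, PFTP and PFHxS. Such orders cannot tell a trend from controls or a highest group that stand apart. The 4 genes of PFHxS had a median departure at 30 µg/L, its lowest concentration, and 0 were called without any 1 plate. A trend with concentration is therefore not claimed for PFHxS. The shares of PFTDoDA and PFTrDA are also under 0.05. For PFTDoDA, however, an order gave 88 genes, several times the real 20, and what that count reflects was not tested. For PFTrDA 2 other orders gave as many, so no more is claimed for these 2. For the 13 substances with 0 genes every order, 100 of 100, gave as many, which a real count of 0 fixes beforehand. The highest other order gave 102 for 4:2FTS, 61 for 6:2FTS, 35 for PFOA and 33 for FC10diol. What these counts reflect was not tested.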
